A study of Homo sapiens with 79 samples.

How the data were processed

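Biopsies of sigmoid colon mucosa came from participants of a randomized trial of intermittent fasting with 2 arms and up to 3 time points. The labels give the arm, the time point and the participant of each of the 79 libraries, and the baseline carries no month. The trial's description names more participants than the 28 whose libraries are analysed here. Per the submitters' processing notes, the reads were demultiplexed with bcl2fastq, aligned to GRCh38 with STAR 2.0.4b and assigned to genes with featureCounts 1.45 of Subread. The annotation release and the strand setting of the counting are not given in the sources used here. Each deposited file lists 62757 features of 1 library, with the read count per gene as the authors produced it, without normalization. The deposited CPM values are the authors' counts scaled to the library total, and were checked to equal the count over the total within a relative difference of 5.1e-15. The deposited RPKM values were made by the authors from CPM and the listed gene length, and were checked within a relative difference of 6.8e-14. Only the counts entered the tests. Of the features, 3945 lie on alternate haplotypes, with 0.132% of all counts. Gene types were taken from GENCODE release 29.

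The comparisons, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined. Genes were kept with edgeR's filterByExpr by arm and time point, which left 19485 genes (17453 in the 28 baseline libraries). Libraries were scaled by TMM. Changes were tested with the quasi-likelihood functions glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3. The model held all 79 libraries with 28 participant terms and 4 terms for time within arm, which leaves 47 residual degrees of freedom. The arms at baseline were compared over 28 libraries without a participant term. Adjusted p values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and all tests are two-sided. Genes of the Y chromosome, XIST and TSIX (539 features) were left out of every test. DESeq2 1.42.0, limma 3.58.1 and sva 3.50.0 served the alternatives.

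A score per library was the mean log2 CPM (prior count 2) over the measured members of each of 49 gene lists with 808 members in all. Changes within participants were tested by exact sign-flip permutation, or by 100000 random flips with more than 20 participants. Differences between the arms were tested by 100000 permutations of the arm labels. These p values were adjusted over the 49 lists of a comparison. A count of members adjusted over the list alone applies Benjamini-Hochberg to edgeR's p values of that list's members. The camera test was run with a preset correlation of 0.01 and with an estimated correlation. Agreement of the arms across genes was tested with 10000 sign flips. Scores, permutations and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

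The named genes were chosen by rule. In each comparison these were the 10 passing genes with the smallest p in each direction or, where fewer than 5 passed, the 5 with the smallest p, said not to have passed. For each list described, up to 4 members with the smallest p were added. In the comparisons at 6 months and over both arms, 24 genes were given whatever their values. Pseudogenes, genes with only a clone name and single immunoglobulin or T cell receptor segments were counted but not named. Some genes that the rule chose are not reported here. As a check of the labels, the nearest other library over the 500 most variable genes belonged to the same participant for 79 of 79 libraries, and the participant terms removed a median of 34.4% of the variance within groups. The tests were tested on simulated data with 200 changed genes; with no simulated change, in the Control arm at 6 months, 0 genes were called. The alternatives were other size factors, filters, tools, covariates, blocks and sets of libraries.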

Results

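Mucosa of the sigmoid colon was biopsied from participants of a randomized trial of intermittent fasting (IF), and RNA from the biopsies was sequenced after oligo-dT selection. The data analysed here cover 28 participants and 79 libraries. In the IF arm there were 14 libraries at baseline, 14 at 6 months and 10 at 12 months. In the Control arm there were 14 at baseline, 14 at 6 months and 13 at 12 months. The IF arm fasted for all 12 months. The Control arm had no intervention for the first 6 months and then crossed over. Its 6 month library is its own reference for the delayed intervention. All 3 time points were present for 23 participants. Each library held 11021898 to 32689179 counted reads (median 16990295). Group medians lay between 16718683 (Control at baseline) and 19124109 (IF at 12 months). Transcripts of the mitochondrial genome took 26.1% ± 3.40 of the counts (mean ± SD, n = 79 libraries). Unless stated otherwise, a change is given as log2 fold change ± standard error (SE) within participants, and levels as CPM (counts scaled to a common library total, mean ± SD over the libraries of a group). Positions are in GRCh38.

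The depth and the number of participants set what could be seen. Among the 10383 genes above 8 CPM, the median SE of a log2 fold change was 0.076 for IF at 6 months against baseline, which gives a 95% interval of ± 0.15. For the difference between the arms the median interval was ± 0.21. Counts were simulated with means, depths and a spread of each gene fitted to the real data. Each gene was drawn on its own, so correlation between genes and outlying libraries were not simulated. In these counts edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment recovered 47 of 50 genes changed 2-fold for IF at 6 months. Of those changed 1.5-fold it recovered 31 of 50. For the difference between the arms it recovered 43 of 50 and 26 of 50. Genes of all simulated folds were changed in the same data, and many true changes make the adjusted threshold easier to reach. These rates therefore do not apply to a gene changed alone or among few. In the real data for IF at 6 months, VIP (fold 0.352) and NSG2 (fold 0.364) did not pass the same test (adjusted p = 0.425 and 0.361).

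**Figure D1:**
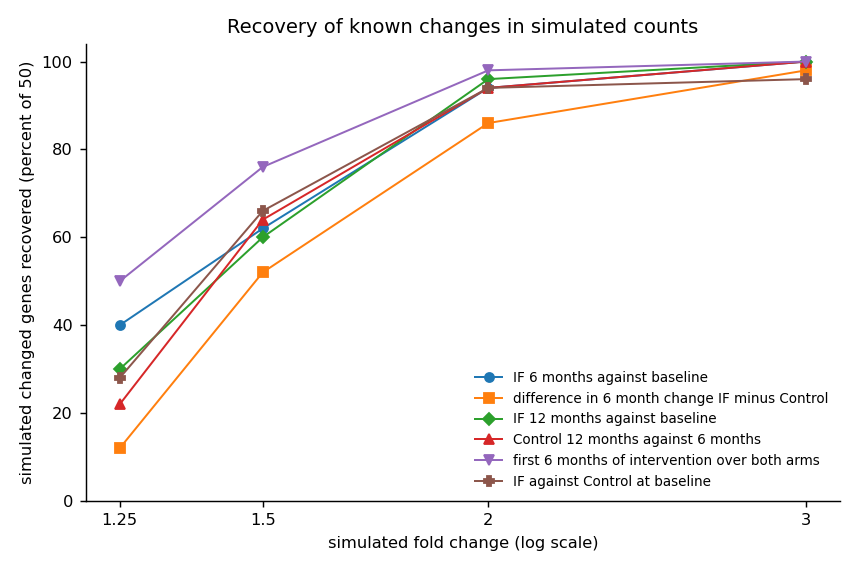
Percent of simulated changed genes recovered (y axis, of 50 genes per fold) against the simulated fold change (x axis, log scale) for 6 comparisons, tested with edgeR's quasi-likelihood test at an adjusted p under 0.05. At a 2-fold change recovery lies between 86% (difference between the arms) and 98% (both arms pooled). Genes of all folds were changed in the same data, so the percentages do not apply to a gene changed alone.

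The change in the IF arm over its first 6 months shows what the mucosa looked like after fasting, each participant against their own baseline. The genes with the smallest p values were MYRF on the higher side and PDE7B, NSG2 and VIP on the lower side. MYRF, a membrane-bound transcription factor (ENSG00000124920, chromosome 11, 61752642 to 61788518), stood at 46.6 ± 9.4 CPM at baseline and 57.7 ± 10.9 CPM at 6 months (n = 14 each), a log2 fold change of 0.32 ± 0.066 that was positive in 11 of 14 participants. VIP, a neuropeptide of enteric neurons (ENSG00000146469, chromosome 6, 152750798 to 152759765), stood at 3.68 ± 2.54 and 1.44 ± 1.63 CPM, a log2 fold change of -1.51 ± 0.35 that was negative in 13 of 14. PDE7B, a phosphodiesterase that degrades cyclic AMP (ENSG00000171408, chromosome 6, 135851696 to 136195574), had 5.61 ± 1.03 and 4.09 ± 1.06 CPM (-0.45 ± 0.10, negative in 13 of 14). None of these passed the test over all genes: with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, MYRF had an adjusted p = 0.18, PDE7B 0.235 and VIP 0.425.

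By that test 0 of 19485 genes passed an adjusted p of 0.05, and 705 had an unadjusted p under 0.05, where evenly spread p values would give about 974. That count depends on the model, with 265 over the same genes without the participant block and 1237 with surrogate variables. With visit labels shuffled within participants, the median of the other splits was 449, below the real count. Of 30 splits, the real labels included, 10 reached 705 or more. DESeq2 called 3 genes, the same MYRF, VIP and PDE7B, with an adjusted p = 0.0246, 0.0388 and 0.0455. Without a filter on low counts edgeR called VIP alone, and limma with quality weights called 0. The other genes named by rule did not pass either. On the higher side these were SMC1B, a cohesin subunit of meiosis (0.59 ± 0.16, p = 4.22e-04, positive in 14 of 14), MYRF-AS1 (0.95 ± 0.26, p = 4.63e-04), CEACAM16 (0.38 ± 0.11, p = 7.17e-04) and the galactosyltransferase gene B3GALT1 (0.31 ± 0.088, p = 8.86e-04). MYRF-AS1 lies antisense to MYRF and the strand setting of the counting is not given, so reads of this pair cannot be told apart. On the lower side were NSG2, a neuronal vesicle protein (-1.46 ± 0.33, p = 5.56e-05, negative in 13 of 14), NEFL, the neurofilament light chain (-1.08 ± 0.27, p = 1.83e-04, negative in 13 of 14), and TMEM59L (-0.93 ± 0.23, p = 1.97e-04). NSG2, NEFL and TMEM59L were all below 1 CPM on average at both times.

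Of the 49 gene lists, 0 passed in this arm, and 7 had an unadjusted p under 0.05 by exact sign-flip permutation over the 14 participants. The enteric glia score (7 measured genes of the supporting cells of gut nerves) had a mean change of -0.22 ± 0.10 on the log2 scale and was negative in 10 of 14 participants (exact permutation p = 0.00916, adjusted p = 0.302). Of its members 2 passed adjusted over the list alone, both lower, and 0 over all genes. The score of 10 smooth muscle markers was at -0.39 ± 0.21 in the same participants (exact permutation p = 0.0618). ACTA2 was at -0.39 ± 0.17 and CNN1 at -0.53 ± 0.26, and 0 members passed under either adjustment. Markers of enteroendocrine cells, the hormone-secreting cells of the epithelium, had a score change of -0.26 ± 0.12, negative in 12 of 14 (exact permutation p = 0.0469, adjusted p = 0.328). Of 15 measured members 3 passed adjusted over the list alone, namely the genes of peptide YY (PYY, -0.44 ± 0.14), somatostatin (SST, -0.59 ± 0.20) and secretagogin (SCGN, -0.38 ± 0.13), and 0 over all genes. For the tuft cell list the change was -0.18 ± 0.073, negative in 11 of 14 (exact permutation p = 0.0298), with SH2D6 (-0.42 ± 0.14, p = 0.00526) the 1 member that passed adjusted over the list alone and 0 over all genes. The list of epithelial inflammation genes lay on the other side, at 0.46 ± 0.20, positive in 11 of 14 (exact permutation p = 0.0123, adjusted p = 0.302). Here 4 of 9 measured members passed adjusted over the list alone, all higher, and 0 over all genes: LCN2, an iron-binding antimicrobial protein, at 0.63 ± 0.19, the elastase inhibitor gene PI3 at 0.65 ± 0.21, DUOXA2 of the epithelial hydrogen peroxide system at 1.52 ± 0.56, and its partner gene DUOX2. The other lists with an unadjusted p under 0.05 were amino acid response genes driven by ATF4 (-0.090 ± 0.035, exact permutation p = 0.0217), MHC class II (-0.15 ± 0.066, p = 0.0309, 4 of 9 members measured) and short-chain fatty acid use (-0.13 ± 0.056, p = 0.0421), each with 0 members passing adjusted over the list alone or over all genes. Single participants weigh on these means: with each left out in turn the glia score was -0.246 to -0.133 (p at most 0.0183), smooth muscle -0.432 to -0.218 and epithelial inflammation 0.296 to 0.524 (p at most 0.0247). The highest p was 0.0938 for enteroendocrine and 0.0596 for tuft cells, 0.0618 for MHC class II and 0.0803 for short-chain fatty acid use.

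Genes of fasting metabolism did not pass. The list of fasting response and fatty acid oxidation (22 measured) had a mean change of 0.056 ± 0.038 (95% interval -0.025 to 0.14, exact permutation p = 0.161), with 0 members passing adjusted over the list alone or over all genes. PDK4, which restrains glucose oxidation, was at -0.019 ± 0.15, ANGPTL4 at 0.10 ± 0.16 and CPT1A, the gate of mitochondrial fatty acid entry, at 0.072 ± 0.064. The scores for insulin, IGF and mTOR signalling (-0.009 ± 0.019), FOXO and sirtuins (0.028 ± 0.034), autophagy and lysosome (0.007 ± 0.032) and the circadian clock (-0.029 ± 0.045) also had intervals that spanned 0. Of the 24 genes chosen whatever their values, 22 were tested and LCN2 was the 1 with an unadjusted p under 0.05 (0.63 ± 0.19, p = 0.00204; it did not pass). The proliferation marker MKI67 was at -0.14 ± 0.18, the stem cell gene LGR5 at -0.13 ± 0.15, the goblet cell mucin MUC2 at 0.15 ± 0.18, IL1B at -0.17 ± 0.27, IGF1 at -0.20 ± 0.12 and SIRT1 at -0.017 ± 0.14. TNF and HSPA1A were below the count filter; both lie in the HLA region, where many genes are listed near 0 in these files, HSPA1A at 0.0132 CPM on average.

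**Figure D2:**
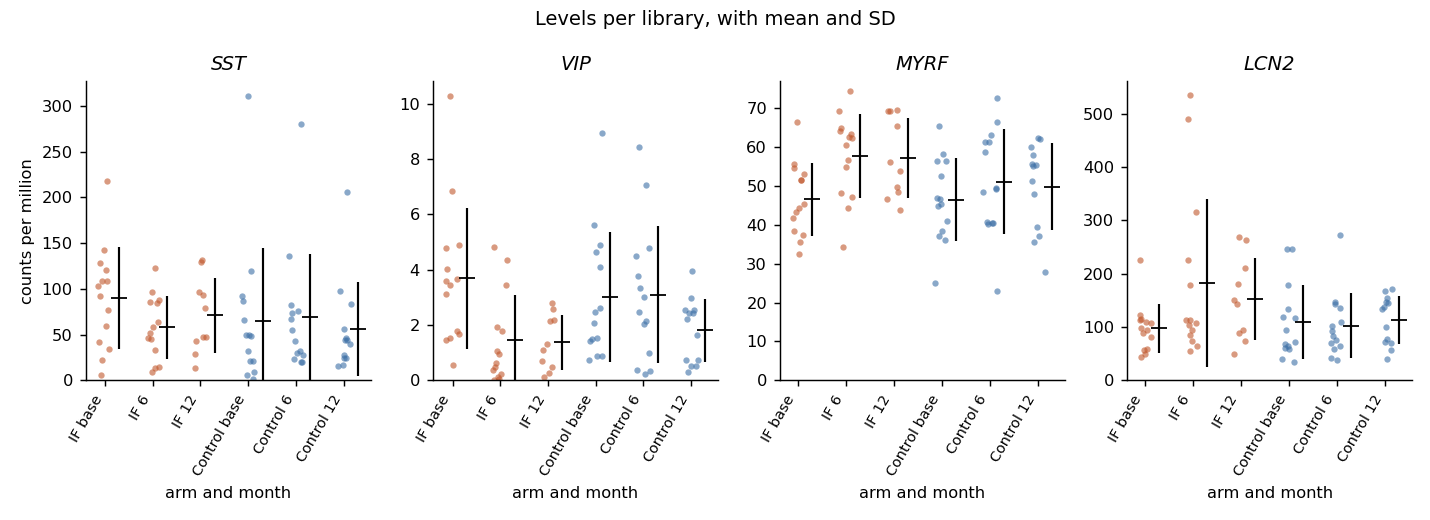
CPM (y axis) of SST, VIP, MYRF and LCN2 in each library of the 6 groups (x axis, arm and month; orange IF, blue Control), with the group mean and SD in black; the axis starts at 0, so an SD that would reach below is not drawn there. VIP averages 3.68 CPM in IF at baseline and 1.44 CPM at 6 months, and MYRF 46.6 and 57.7 CPM.

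The Control arm over the same 6 months, without intervention, measures what changes between visits when nothing is done. Its cell cycle genes stood lower at 6 months. MKI67 had 93 ± 64.3 CPM at baseline and 56.2 ± 17.1 at 6 months (n = 14 each, -0.50 ± 0.18, negative in 10 of 14), and UBE2C, which drives exit from mitosis (chromosome 20, 45812576 to 45816957), was at -0.54 ± 0.17. Of the 26 proliferation genes, 25 passed adjusted over the list alone, all lower, and 0 over all genes. Members of this list vary together (correlation 0.772 as camera estimated it over the 79 libraries), so they are not separate observations. The score of that list, tested over participants, was at -0.42 ± 0.20 and negative in 11 of 14 (exact permutation p = 0.0447, adjusted p = 0.376), so the list did not pass. Other members were CDC20 at -0.57 ± 0.18, CCNA2 at -0.60 ± 0.20 and BIRC5 at -0.59 ± 0.20.

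Over all genes 0 of 19485 passed with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 977 had an unadjusted p under 0.05, and DESeq2 and limma with quality weights called 0 as well. With limma 1729 had an unadjusted p under 0.05, against 533 in edgeR without the participant block. Among the genes with the smallest p values were SLC46A1, the proton-coupled folate transporter (0.56 ± 0.14, p = 3.08e-04), LINC02701 (0.59 ± 0.16, p = 4.58e-04), CACNA2D2 (0.40 ± 0.12, p = 9.64e-04) and NWD1 (0.37 ± 0.11, p = 0.00118) on the higher side. The lower side held ANKRD36C (-0.39 ± 0.10, p = 2.98e-04), the condensin gene NCAPG (-0.77 ± 0.21, p = 4.98e-04), SGO2, which protects centromere cohesion (-0.56 ± 0.15, p = 5.08e-04), GALNT14 (-1.28 ± 0.35, p = 6.74e-04, negative in 13 of 14) and SLC1A4 (-0.21 ± 0.058, p = 8.12e-04). Reads of ANKRD36C can be shared with its close paralogs. Among the other lists, the circadian clock score was at 0.13 ± 0.065 (positive in 9 of 14, exact permutation p = 0.0265, adjusted p = 0.376), with PER3 at 0.26 ± 0.12 and NR1D2 at 0.21 ± 0.10 and 0 of 19 members passing adjusted over the list alone or over all genes. The distal colon position genes were at 0.32 ± 0.20 (positive in 10 of 14, exact permutation p = 0.0437), and HOXD10 (0.45 ± 0.16) and HOXD11 (0.37 ± 0.14) passed adjusted over the list alone, 0 over all genes. With each participant left out in turn the distal colon score was 0.125 to 0.367 and the circadian clock score 0.079 to 0.156. Immediate early genes, which respond quickly to stimuli, were at 0.41 ± 0.23 (positive in 12 of 14, exact permutation p = 0.0614), with FOS at 0.86 ± 0.34 and 0 members passing under either adjustment. The crypt base list was at 0.13 ± 0.060, with LGR5 at 0.33 ± 0.15, p = 0.034. Heat shock proteins (-0.10 ± 0.041, exact permutation p = 0.0312) and autophagy and lysosome genes (0.048 ± 0.021, p = 0.0405) complete the 5 lists with an unadjusted p under 0.05, of which 0 passed. Glia (0.051 ± 0.079), enteroendocrine (0.28 ± 0.20) and smooth muscle (-0.10 ± 0.23) scores had intervals across 0. Single participants moved them as well: with each left out in turn they were 0.014 to 0.091, 0.161 to 0.345 and -0.267 to -0.023.

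The randomized comparison sets the 6 month change of the IF arm against that of the Control arm. Enteroendocrine markers were among 8 lists with an unadjusted p under 0.05: the change of their score in IF minus that in Control was -0.54 ± 0.23, with 12 of 14 IF participants below 0 and 9 of 14 Control participants above it. By permutation of the arm labels p = 0.023, and over the 49 lists adjusted p = 0.267, so the list did not pass. Of its 15 measured members 8 passed adjusted over the list alone, all lower in IF, and 0 over all genes. They include SCGN (chromosome 6, 25652201 to 25701783) at -0.68 ± 0.18, SST (chromosome 3, 187668906 to 187670399) at -0.95 ± 0.28, PYY (chromosome 17, 43952738 to 44004469) at -0.66 ± 0.20 and INSL5, a hormone of colonic endocrine cells (chromosome 1, 66797741 to 66801256), at -1.01 ± 0.31. SCGN stood at 11.6 ± 3.95 and 8.9 ± 3.13 CPM in IF at baseline and 6 months and at 8.76 ± 4.82 and 10 ± 3.86 CPM in Control. At baseline the same score stood higher in IF than in Control by 0.56 ± 0.30 (permutation p = 0.0748).

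With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment 0 of 19485 genes passed for this difference. An unadjusted p under 0.05 was reached by 641 genes, and DESeq2 and limma with quality weights called 0. The genes with the smallest p were GALNT14 (1.77 ± 0.48, p = 5.86e-04), GPR82 (0.55 ± 0.17, p = 0.00157), FAM81A (0.62 ± 0.19, p = 0.00191), SRPX2 (0.39 ± 0.12, p = 0.00216) and the receptor kinase gene TYRO3 (0.55 ± 0.18, p = 0.00325) on the higher side. SCGN (4.77e-04) led the lower side, followed by DNAJC27-AS1 (-0.90 ± 0.25, p = 7.97e-04), SPTBN4 (-0.56 ± 0.16, p = 9.84e-04), THBS4 (-0.64 ± 0.19, p = 0.00103) and CPLX2, a regulator of vesicle release (-0.67 ± 0.20, p = 0.00135). GALNT14 was below 1 CPM in all 4 groups, and its difference came with 13 of 14 Control participants below 0 and 7 of 14 IF participants above.

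Of the 49 lists 8 had an unadjusted p under 0.05 and 0 passed. Beside the enteroendocrine list these were tuft cell markers (-0.23 ± 0.094, permutation p = 0.0213; TRPM5 -0.47 ± 0.17), crypt base and WNT targets (-0.22 ± 0.091, p = 0.0266; LGR5 -0.46 ± 0.21, EPHB3 -0.49 ± 0.20), distal colon position (-0.39 ± 0.21, p = 0.0289), enteric glia (-0.27 ± 0.12, p = 0.0305), immediate early genes (-0.57 ± 0.28, p = 0.0327), the circadian clock (-0.16 ± 0.079, p = 0.0385; PER3 -0.47 ± 0.18) and short-chain fatty acid use (-0.19 ± 0.089, p = 0.0437). Of these further lists the glia list had 2 members passing adjusted over the list alone, both lower, and the others 0; over all genes 0 passed in each. With each participant left out in turn the 8 lists kept their sign. At least once p was 0.05 or more for distal colon (nearest to 0 at -0.198), glia (-0.185), immediate early (-0.366), circadian clock (-0.108) and short-chain fatty acid (-0.154) lists. The adjusted p of each of the 8 lists was 0.267. For the immediate early and distal colon lists the Control arm alone was at 0.41 ± 0.23 and 0.32 ± 0.20, against -0.16 ± 0.14 and -0.074 ± 0.073 in IF. Fasting response and fatty acid oxidation differed by 0.062 ± 0.072 (95% interval -0.086 to 0.21). Among the 22 tested genes chosen whatever their values, LGR5 (-0.46 ± 0.21, p = 0.0374) and LCN2 (0.65 ± 0.27, p = 0.021) had an unadjusted p under 0.05. CPT1A differed by 0.13 ± 0.091, MKI67 by 0.36 ± 0.26 and PER1 by -0.45 ± 0.26.

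**Figure D3:**
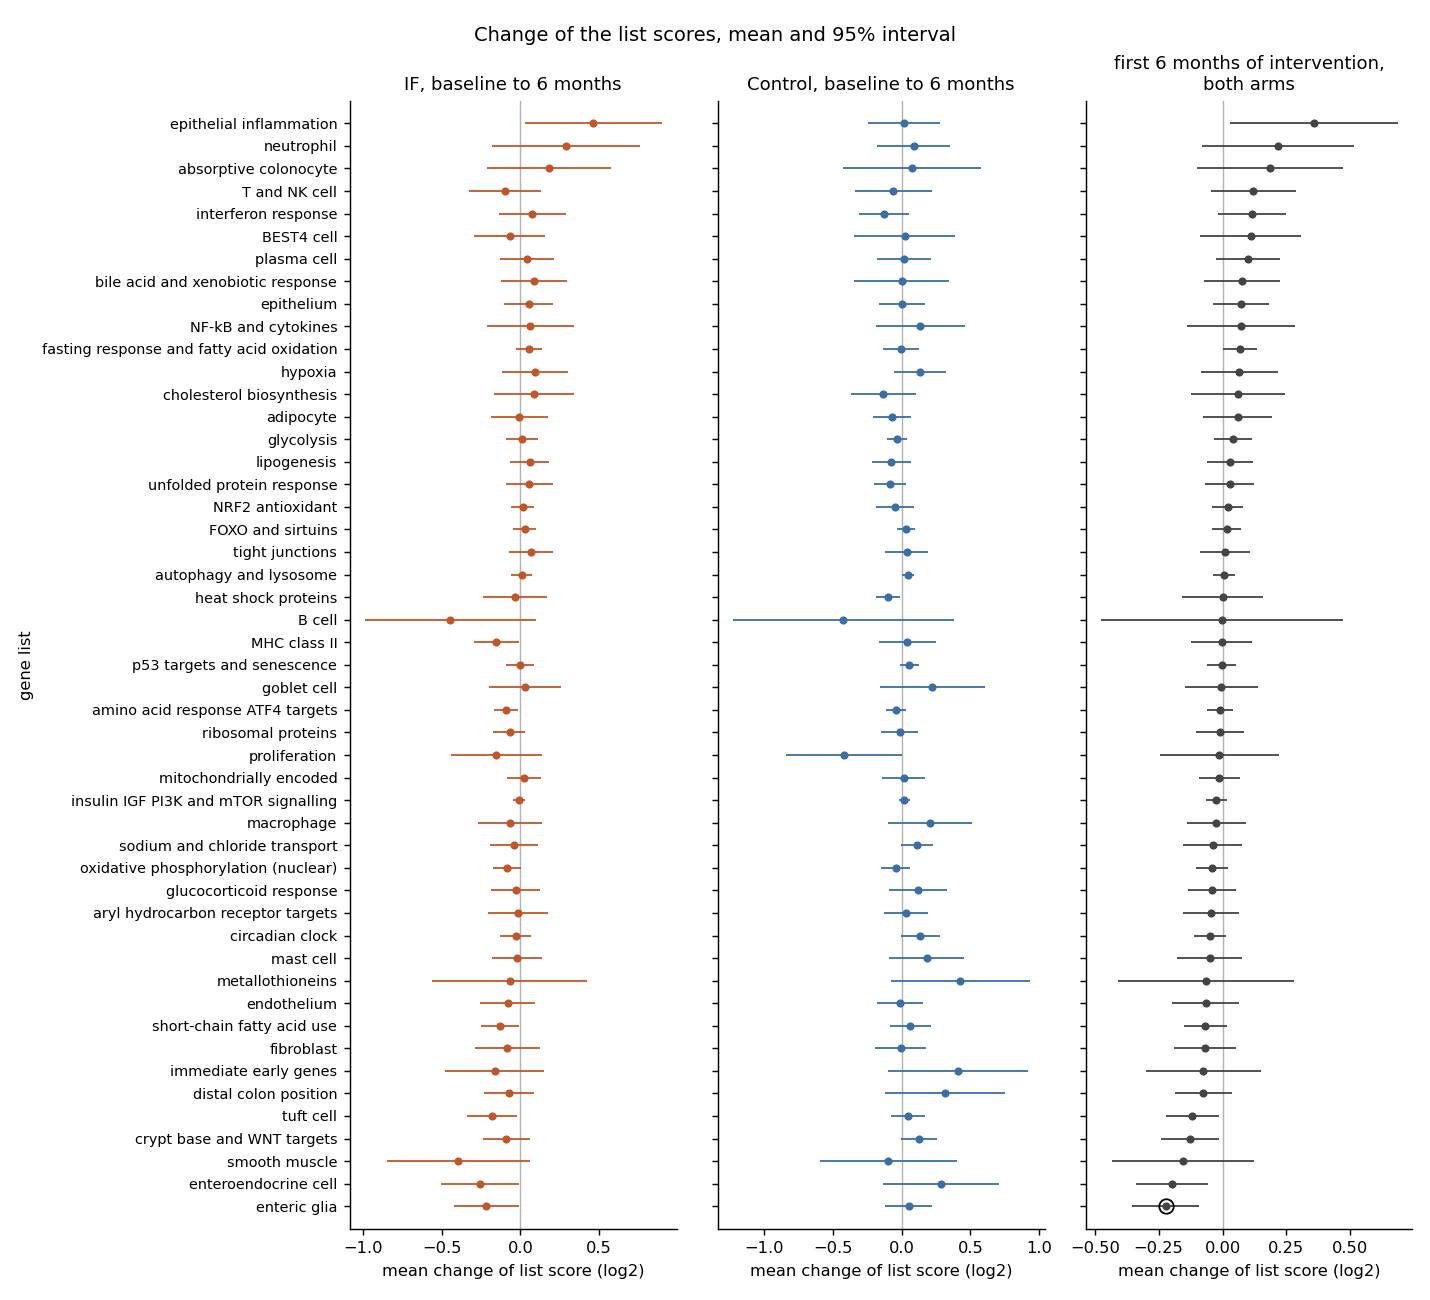
Mean change of the score of each of 49 gene lists (y axis) on the log2 scale (x axis; scales differ between panels) with 95% intervals for IF and Control over the first 6 months and for the first 6 months of intervention over both arms. The black ring marks the 1 list that passed over the 49 lists, enteric glia over both arms at -0.222.

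After 12 months of fasting, 10 IF participants could be set against their own baseline. Neither arm went without intervention for all 12 months, so a drift with visit cannot be told apart from fasting in these changes. GAP43, a growth-associated protein of axons (ENSG00000172020, chromosome 3, 115623324 to 115721490), had 0.732 ± 0.409 CPM at baseline and 0.242 ± 0.205 at 12 months (n = 14 and 10 libraries), a log2 fold change of -1.75 ± 0.36 that was negative in 9 of 10 participants. VIP was at -1.51 ± 0.40, negative in 10 of 10, and NSG2 at -1.51 ± 0.36, negative in 9 of 10. NEUROG3, the transcription factor that starts endocrine cell differentiation (chromosome 10, 69571698 to 69573238), had 1.47 ± 0.608 and 0.816 ± 0.515 CPM (-0.77 ± 0.20, negative in 9 of 10). On the higher side the long noncoding RNA LINC02362 (chromosome 4, 184365183 to 184382306) was at 0.54 ± 0.11 in 10 of 10 participants.

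None passed with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment: the smallest adjusted p, 0.117, belonged to LINC02362 and GAP43, 0 of 19485 genes passed and 962 had an unadjusted p under 0.05, of which 669 were higher. DESeq2 called 2, LINC02362 and GAP43. Limma with quality weights called 10 (8 higher and 2 lower) and had 2404 genes at an unadjusted p under 0.05, against 295 in edgeR without the participant block. EdgeR without a filter called CXCL5, GAP43 and VIP. CXCL5, a chemokine that attracts neutrophils, had 0.329 ± 0.314 and 3.33 ± 8.24 CPM (2.46 ± 0.56) and was higher in 6 of 10 participants. In 1 library of this group, replicate 6, the neutrophil, NF-kB and interferon scores were all the highest of the 10 and stood apart from the other 9. Without it CXCL5 was at 1.77 (p = 0.00339, adjusted p = 0.898), so much of its value rests on that library. EdgeR's count was again 0, with 904 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.298. Further genes by rule were C2orf92 (0.48 ± 0.11, p = 4.1e-05), BTNL9 (0.40 ± 0.10, p = 2e-04), CCNL2 (0.23 ± 0.060, p = 3.39e-04) and RMND1 (-0.26 ± 0.070, p = 5.46e-04, negative in 10 of 10).

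No list passed at 12 months, and 3 had an unadjusted exact permutation p under 0.05. The plasma cell score was at 0.090 ± 0.035 (positive in 8 of 10, exact permutation p = 0.0332, adjusted p = 0.555), with MZB1 at 0.23 ± 0.11 and 0 members passing adjusted over the list alone or over all genes. Lipogenesis was at 0.10 ± 0.038 (positive in 8 of 10, exact permutation p = 0.0332), with SREBF1, its master regulator, at 0.22 ± 0.089 and again 0 members passing. Enteroendocrine markers were at -0.21 ± 0.094, negative in 8 of 10 (exact permutation p = 0.0488), with SCG2 at -0.44 ± 0.16 and 0 passing. Epithelial inflammation was at 0.47 ± 0.21 (exact permutation p = 0.0566), where LCN2 (0.64 ± 0.22) passed adjusted over the list alone and 0 members over all genes. Proliferation was at -0.24 ± 0.12 (exact permutation p = 0.0547; AURKA -0.34 ± 0.11). The glia score was at -0.046 ± 0.12 with a 95% interval of -0.32 to 0.23.

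The delayed intervention of the Control arm, 12 months against 6 months in 13 participants, is the first 6 months of fasting in other participants. No arm went without intervention over these months, so a drift with visit cannot be told apart from fasting here. Glial markers were among those furthest below 0: the enteric glia score was at -0.23 ± 0.084, negative in 9 of 13 (exact permutation p = 0.0134, adjusted p = 0.538). Of its 7 members 2 passed adjusted over the list alone, both lower, and 0 over all genes. The smooth muscle score was at 0.084 ± 0.17 over the same interval, and at 0.019 to 0.216 with each participant left out in turn. T and NK cell markers stood higher, at 0.34 ± 0.12 and positive in 10 of 13 (exact permutation p = 0.022, adjusted p = 0.538), with NKG7 at 0.46 ± 0.17 and CD2 at 0.45 ± 0.17. Of its 16 measured members 8 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone or over all genes.

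The single genes with the smallest p on the higher side were SULT2B1, a sulfotransferase of cholesterol (chromosome 19, 48552075 to 48599425; 1.7 ± 1.63 to 2.47 ± 2.66 CPM, 0.55 ± 0.11, p = 8.59e-06, positive in 11 of 13), the chemokine receptor gene CXCR3 (0.58 ± 0.14, p = 1.08e-04, positive in 11 of 13), UNC13D, which primes cytotoxic granules (0.37 ± 0.091, p = 1.89e-04), RELL2 (0.43 ± 0.12, p = 8.72e-04) and CORO1A-AS1 (0.76 ± 0.22, p = 9.08e-04), which lies antisense to CORO1A, so reads of the pair cannot be told apart without the strand setting. On the lower side were NAPB (-0.20 ± 0.053, p = 4.62e-04), MATCAP2 (-0.63 ± 0.17, p = 4.87e-04), KANK1 (-0.21 ± 0.060, p = 0.00116), the neuronal kinesin gene KIF5C (-0.49 ± 0.14, p = 0.00118, negative in 12 of 13) and ZFAND1 (-0.16 ± 0.046, p = 0.00122). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment 0 of 19485 genes passed (SULT2B1 had the smallest adjusted p = 0.167), 918 had an unadjusted p under 0.05, and DESeq2 and limma with quality weights called 0. The list of fasting response and fatty acid oxidation was at 0.079 ± 0.053 (positive in 6 of 13, exact permutation p = 0.154). Its members CPT1A (0.19 ± 0.066, p = 0.00467) and ACAA2 (0.26 ± 0.10, p = 0.00972) did not pass adjusted over the list alone or over all genes. Crypt base markers were at -0.17 ± 0.085 (LGR5 -0.37 ± 0.16) and BEST4 cell markers at 0.29 ± 0.16 (OTOP2 0.54 ± 0.25), neither past the test.

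Pooling the first 6 months of intervention of both arms uses 27 participants and 4 groups with no library in common. Enteric glia markers fell: the score changed by -0.22 ± 0.063 (95% interval -0.35 to -0.092), negative in 10 of 14 IF and 9 of 13 Control participants (permutation p = 1.7e-04, adjusted p = 0.00833 over 49 lists), the 1 list that passed in any of the 7 comparisons. The adjustment covers the lists of 1 comparison, and none was made over the 7 comparisons together. CDH19, a cadherin gene (ENSG00000071991, chromosome 18, 66501083 to 66604138), was at -0.32 ± 0.11. It had 2.61 ± 1.12 and 2.09 ± 0.771 CPM in IF before and after, and 3 ± 1.4 and 2.24 ± 1.01 in Control. Of the 7 members 5 passed adjusted over the list alone, all lower, and 0 over all genes.

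With the correlation of the members estimated from the data, camera gave the glia list an adjusted p = 0.034. Leaving out each of the 27 participants in turn gave score changes of -0.237 to -0.181 and adjusted p values of 0.00294 to 0.0152. In the same intervals smooth muscle markers were at -0.15 ± 0.14, fibroblast markers at -0.069 ± 0.059 and endothelium at -0.066 ± 0.064, none past the test, while epithelium (0.073 ± 0.053) and plasma cells (0.10 ± 0.061) lay above 0. With each participant left out in turn the smooth muscle change was -0.187 to -0.067, fibroblasts -0.084 to -0.028 and endothelium -0.086 to -0.030. In the Control arm before intervention the glia score was at 0.051 ± 0.079. Among the 22 tested genes chosen whatever their values, LGR5 (-0.25 ± 0.11, p = 0.0268) joined CPT1A and LCN2 with an unadjusted p under 0.05.

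**Figure D4:**
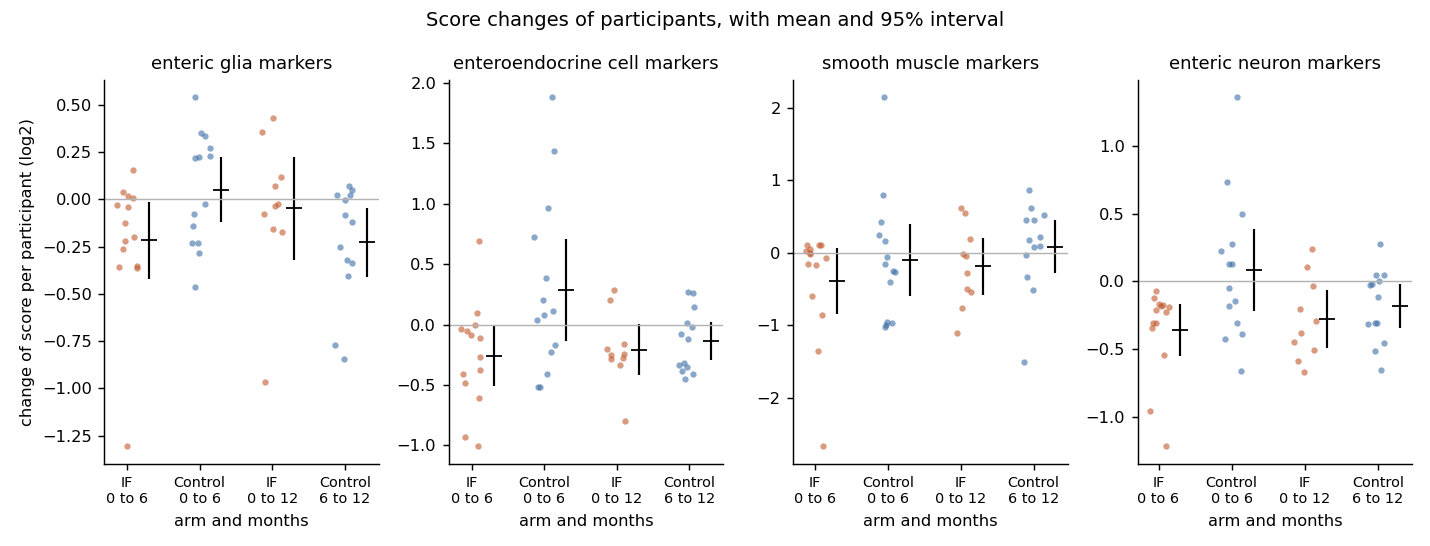
Change of 4 marker scores in each participant (y axis, log2; scales differ between panels) for both arms and intervals (x axis, arm and months), with the mean and 95% interval in black. The glia score averages -0.217 in IF from baseline to 6 months and -0.228 in Control from 6 to 12 months, against 0.051 in Control before intervention.

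The enteroendocrine score was next, at -0.20 ± 0.068 and negative in 12 of 14 IF and 9 of 13 Control participants (permutation p = 0.00729, adjusted p = 0.179), which did not pass. Of 15 measured members 6 passed adjusted over the list alone, all lower, and 0 over all genes, with SST at -0.47 ± 0.14, SCGN at -0.28 ± 0.092, the prohormone-processing gene CPE at -0.20 ± 0.066 and PYY at -0.29 ± 0.10. Epithelial inflammation was at 0.36 ± 0.16 (positive in 11 of 14 IF and 8 of 13 Control participants, permutation p = 0.027, adjusted p = 0.277). Its members PI3 (0.58 ± 0.15), DUOXA2 (1.19 ± 0.41), LCN2 (0.40 ± 0.14) and DUOX2 (0.97 ± 0.35) passed adjusted over the list alone and 0 members over all genes. Crypt base markers were at -0.13 ± 0.055 (permutation p = 0.0273). SMOC2 (-0.22 ± 0.073) and ZNRF3 (-0.19 ± 0.064) passed adjusted over the list alone, and 0 members over all genes. Tuft cell markers were at -0.12 ± 0.051 (permutation p = 0.0283), and 0 passed under either adjustment. Fasting response and fatty acid oxidation was at 0.068 ± 0.033 (permutation p = 0.0436, adjusted p = 0.356), with CPT1A (0.13 ± 0.046, p = 0.00538), ACAA2 (0.17 ± 0.069, p = 0.0182) and the fasting-induced regulator CREB3L3 (0.69 ± 0.30, p = 0.0237) among 4 members with an unadjusted p under 0.05 and 0 passing adjusted over the list alone or over all genes.

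Over all genes 0 of 19485 passed with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 982 had an unadjusted p under 0.05, and DESeq2 and limma with quality weights called 0. Without the count filter edgeR called 6 genes, among them VIP, KIF5C and SST, which were lower, and PI3 and CDHR2, which were higher. The smallest adjusted p with the filter was 0.481, shared by genes that included NEUROG3 (-0.53 ± 0.12, negative in 13 of 14 IF and 9 of 13 Control participants), VIP (-1.08 ± 0.25), KIF5C (-0.41 ± 0.10) and PDE7B (-0.28 ± 0.071) on the lower side and UNC13D (0.26 ± 0.064) on the higher. PI3, MSLN (0.31 ± 0.086), the brush border protocadherin gene CDHR2 (0.49 ± 0.14) and MYRF (0.17 ± 0.047) followed. In Control, VIP was lower in 7 of 13, PDE7B in 7 of 13 and MYRF higher in 7 of 13.

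Whether the arms changed alike gene by gene was tested across 19485 genes. For this test a change was the mean over participants of the change in log2 CPM. The IF change from baseline to 6 months and the Control change from 6 to 12 months had a Pearson correlation of 0.037 and a Spearman correlation of 0.010 across genes, which are not independent replicates. Random flips of the participants' changes gave p = 0.801 and p = 0.955 (permutation, 10000 flips), with 95% of chance values for Pearson between -0.278 and 0.279. The sign was shared by 48.8% of genes. Of the further contrasts, IF at 12 against 6 months, Control at 12 months against baseline, and the IF change minus the delayed Control change each had 0 genes with edgeR and 0 with DESeq2, with 706, 1172 and 677 at an unadjusted p under 0.05 in edgeR.

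**Figure D5:**
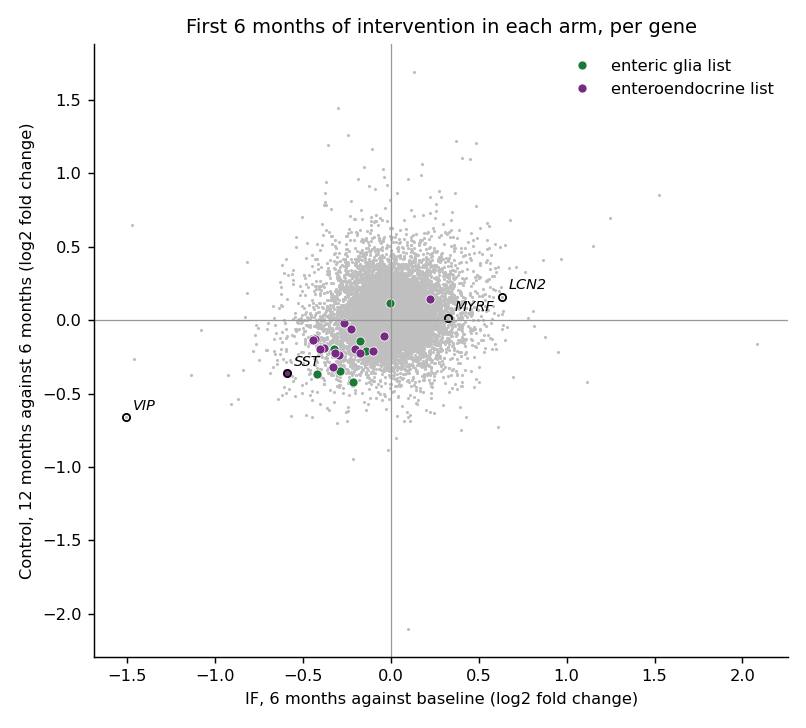
Log2 fold change of each of 19485 genes in IF at 6 months against baseline (x axis) and in Control at 12 against 6 months (y axis); green points are the enteric glia list, purple points the enteroendocrine list, and ringed points are labelled. The Pearson correlation of 0.037 was computed from mean changes of log2 CPM over participants, not from the plotted fold changes. SST and VIP lie below 0 on both axes.

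At baseline randomized arms should differ only by chance, and the comparison of 14 with 14 libraries looks at this. How these participants were chosen from those of the trial is not given in the sources used here, so an effect of selection is not excluded. Metallothioneins, which bind zinc and copper, were the list furthest apart, with a score higher in IF by 0.70 ± 0.26 (permutation p = 0.0121, adjusted p = 0.594), so no list passed. Of 9 members 6 passed adjusted over the list alone, all higher in IF, and 0 over all genes. MT1X had 49.5 ± 22.2 CPM in Control and 85.8 ± 24.4 in IF (0.78 ± 0.22) and MT1E 294 ± 106 and 467 ± 137 CPM (0.65 ± 0.19), with MT2A at 0.62 ± 0.25. Members of this family are near copies of each other, so their single values are uncertain. The enteroendocrine score was higher in IF by 0.56 ± 0.30 (permutation p = 0.0748; INSL5 1.16 ± 0.45, PYY 0.69 ± 0.29), with 5 members at an unadjusted p under 0.05 and 0 passing adjusted over the list alone or over all genes.

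With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment 0 of 17453 genes passed, and DESeq2 and limma with quality weights called 0. An unadjusted p under 0.05 was reached by 340 genes, where evenly spread p values would give about 873. With arm labels shuffled the median of the other splits was 727, and 88 of 100 splits reached 340 or more. By rule, the genes higher in IF were MPPED2 (0.90 ± 0.19, p = 6.21e-05), ACOT1 (0.72 ± 0.18, p = 4.8e-04), the cartilage collagen gene COL2A1 (0.88 ± 0.24, p = 8.84e-04), MT1X and MT1E. Lower in IF were LGSN (-2.49 ± 0.64, p = 5.34e-04), CD177, a surface protein best known from neutrophils (262 ± 153 CPM in Control and 97.6 ± 67.3 in IF, -1.46 ± 0.38, p = 5.63e-04), PHACTR2-AS1 (-0.45 ± 0.12, p = 9.42e-04), LRRCC1 (-0.32 ± 0.10, p = 0.0026) and YBX2 (-0.57 ± 0.17, p = 0.00266). ACOT1 and CD177 have close paralogs or pseudogenes with which reads can be shared.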

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

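The tests of a drift with visit, of a lasting response and of nerve markers were chosen after the result was seen, as was the neuron list itself. In the 10 IF libraries at 12 months 52 measures were examined for a library apart from the rest, and 5 had one, where chance gives about 1 in 20. The gap of the extreme library over the range of the group was 0.506 for the neutrophil score (highest library), 0.598 for NF-kB and cytokines (highest), 0.708 for the interferon response (highest), 0.495 for heat shock proteins (lowest) and 0.604 for metallothioneins (lowest), against a critical value of 0.466. Replicate 6 was the extreme library for the neutrophil, NF-kB and interferon scores, and not for the other measures.

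Enteric glia markers fell over the first 6 months of intervention in both arms pooled, by 0.222 on the log2 scale. With 3 stromal scores regressed out the change was -0.151 ± 0.028 (permutation p = 2e-05), so changes of these scores did not account for all of it. The scores did account for much of the variation between participants (R squared 0.805). They are indirect measures of depth taken from the same libraries, so less of the deeper wall was not excluded. A drift with visit shared by the arms would leave no difference between them over the first 6 months. The 6 month change of the glia score in IF minus that in Control was -0.268 ± 0.123 (permutation p = 0.0305, unadjusted). Adjusted over the lists of that comparison it did not pass (adjusted p = 0.267). This difference rests on few participants: with each of the 28 left out in turn it was -0.308 to -0.185, and in 4 of these p was 0.05 or more (highest 0.0611). It does not cover the Control change from 6 to 12 months, where no arm went without intervention. A drift with visit was therefore not excluded for the pooled change. Fewer nerve elements of any kind may be a candidate explanation. A score of neuron markers, 11 measured of 19 listed, changed by -0.268 ± 0.058 (permutation p = 1e-05, the smallest possible). With the 3 stromal scores regressed out it changed by -0.224 ± 0.047 (permutation p = 2e-05). The list left out the nerve genes seen first but was written after them. These p values are therefore not independent of that choice. Whether the response lasts stays open, with -0.046 ± 0.121 in IF at 12 months and a 95% interval of -0.319 to 0.227. Its sign rests on 1 participant, without whom it was 0.056. The depth of the biopsies, which the labels do not give, was not tested directly. The neuron score therefore cannot tell fewer nerve elements in the tissue from less of the deeper wall in the biopsies.

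The arms differed in the neuron score, whose 6 month change in IF minus Control was -0.441 ± 0.166 (permutation p = 0.00904), negative in 14 of 14 IF and 7 of 14 Control participants. Its list was written after VIP and other nerve genes had been seen, so this p value is not independent of that choice. A score of the 5 glia and nerve genes seen first was at -0.248 ± 0.162 in Control at 12 against 6 months (negative in 9 of 13, exact permutation p = 0.139).

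The 6 month change of the enteroendocrine score in IF minus that in Control was -0.54 on the log2 scale, a list that did not pass. A baseline difference between the arms is a candidate explanation: adjusted for the baseline score, the difference was -0.226 ± 0.165 (permutation p = 0.178). An effect of the intervention on these cells was not excluded.

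Some abundant genes of the colon are listed near 0, such as HLA-DRA at 0.00141 CPM and KRT20 at 0.316 CPM. Reads shared with copies on alternate haplotypes may be the cause: 441 of 514 protein coding genes with such a copy were under 1 CPM, against 5466 of 19048 without, a ratio of shares of 2.99. The genes with and without a copy were not matched by their expression in this tissue. The ratio alone therefore cannot tell shared reads from low expression. MYH11 (0.311 CPM), IRF7 (0.289 CPM) and ACACA (0.206 CPM) had no matched copy, so their low values stay open.

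Whether chance can be excluded was examined by other splits of the libraries. The real count of genes was 0 in each of the 10 comparisons, which any split matches, so the splits say nothing about chance for these counts and it was not excluded. They were 30 splits of the visits within participants, 60 of the arms for the difference in change and 100 of the arms at baseline. The real count at an unadjusted p under 0.05 was reached by 10 to 15 of the 30 splits of the visits. It was reached by 27 of 60 for the difference in change and 88 of 100 at baseline, so chance was not excluded for these counts either. The highest count among the other splits was 0 for IF at 6 months, 123 for Control at 6 months, 1 for the difference in change, 779 for IF at 12 months, 1 for Control at 12 against 6 months, 0 over both arms and 1165 for the arms at baseline. For the further contrasts it was 534 for IF at 12 against 6 months and 0 for the other 2. Few splits called any gene: 3 of 30 for Control at 6 months, 2 of 60 for the difference in change, 2 of 30 each for IF at 12 months, Control at 12 against 6 months and IF at 12 against 6 months, 9 of 100 at baseline and 0 in the other 4 comparisons. Those with many genes may point to a structure of the samples other than arm and visit, which was not tested.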

How the results depend on the processing

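The bias-adjusted quasi-likelihood fit and the sets of libraries left out were chosen after the data were seen, as was leaving out each participant in turn. Of 95 gene counts under an alternative, 80 planned and 15 added, 86 were 0 like the reported counts and 9 were above 0, the highest 10. For IF at 6 months, no filter on low counts (48517 genes) gave 1 gene and DESeq2 gave 3. For IF at 12 months, no filter gave 3, DESeq2 2, limma with quality weights 10, marker scores as covariates 2 and bias-adjusted deviances 2. Over both arms no filter gave 6. In each of these the cause was not tested.

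Leaving the participant block out (no replicate block) gave 1 gene for IF at 12 months, CXCL10, and 0 in the other comparisons with a block; the cause was not tested. Over the same genes, the count at an unadjusted p under 0.05 ran over the alternatives from 238 to 1012 for the difference in change, 303 to 1060 for Control at 12 against 6 months, 349 to 1216 over both arms and 341 to 822 at baseline. Without the 2 libraries that stand apart, the 1 with the highest mitochondrial share (40.8%) and the 1 farthest on the first principal component, each count was 0 and the glia list over both arms kept its call (-0.227, adjusted p = 0.00833).

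Over the 49 lists and 7 comparisons, with each comparison adjusted on its own, 1 call was made. The median over members and other size factors each gave 1 call, and camera with an estimated correlation gave 1. With a preset correlation of 0.01 camera gave 141 calls. The 2 camera runs differed only in that correlation, so the difference in calls comes from it. Over both arms the estimate was 0.353 for the glia list and ran from 0.00109 (adipocyte) to 0.882 (B cell). Leaving out each participant in turn gave 1 to 2 calls. Adjusting for the change in the epithelium score gave 3 calls, 1 in Control at 12 against 6 months and 2 over both arms, glia among them (-0.169, adjusted p = 0.0292). For the participants left out and the epithelium adjustment the cause was not tested. The correlation between the arms ranged from 0.009 to 0.060 (Pearson) over its alternatives, none past the threshold.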

Other observations

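The neuron list and the tests of its score were chosen after VIP and other nerve genes had been seen, except the test against enteroendocrine cells. Its markers were lower in IF at 6 months for 11 of 11 measured genes and over both arms for 10, of which 6 had an unadjusted p under 0.05 by edgeR. PRPH, a filament protein of peripheral neurons, was at -0.69 ± 0.21 in IF and -0.53 ± 0.15 over both arms, UCHL1 at -0.77 ± 0.24 and -0.44 ± 0.17, and the neuropeptide gene GAL at -0.91 ± 0.39 and -0.74 ± 0.27. RET, a receptor needed for enteric nerve development, was at -0.30 ± 0.094 and SYT1, a calcium sensor of synaptic vesicles, at -0.32 ± 0.097 over both arms. STMN2, the most abundant at 20.3 CPM on average, was at -0.10 ± 0.065, and 5 of the 11 were above 1 CPM. In IF at 6 months the score was at -0.356 ± 0.089 and negative in 14 of 14 (exact permutation p = 1.22e-04, the smallest possible), while smooth muscle markers in the same participants were at -0.39 ± 0.21. Over both arms the neuron score was at -0.224 ± 0.047 (permutation p = 2e-05) with the smooth muscle, fibroblast and endothelium scores regressed out, against -0.268 before. Unadjusted, it was at -0.276 in IF at 12 months (negative in 8 of 10, exact permutation p = 0.0254), at -0.18 in Control at 12 against 6 months (negative in 9 of 13, exact permutation p = 0.0308) and at 0.085 in Control before intervention (exact permutation p = 0.575). With each participant left out in turn, the last value was -0.013 to 0.142, its sign turning without 1 participant. The highest p was then 0.0508 in IF at 12 months, 0.0615 in Control at 12 against 6 months and 2.44e-04 in IF at 6 months.

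A hypothesis is that fewer enteroendocrine cells, which share secretory genes with neurons, could account for the lower neuron score. With the change of the enteroendocrine score regressed out, the neuron score over both arms was at -0.308 ± 0.056 (permutation p = 1e-05, the smallest possible), against -0.268 before, which argues against it. NEFM was moved out of the neuron list after a score that held it had been seen, and with NEFM the change over both arms was -0.288 ± 0.059.

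Of the immune, metabolic and epithelial lists not described so far, none passed over the first 6 months of intervention in both arms. The neutrophil score was at 0.22 ± 0.14 (permutation p = 0.142), as far from 0 as the glia score but with a wider spread. Of its 11 members 4 were measured, and 2 passed adjusted over the list alone, both higher, and 0 over all genes. The interferon response score was at 0.12 ± 0.065 (permutation p = 0.0867), NF-kB and cytokines at 0.071 ± 0.10, macrophages at -0.025 ± 0.056 and B cells at -0.003 ± 0.23. Cholesterol synthesis was at 0.060 ± 0.089 with a 95% interval of -0.12 to 0.24, glycolysis at 0.042 ± 0.036 (-0.033 to 0.12), nuclear genes of oxidative phosphorylation at -0.040 ± 0.031 (-0.10 to 0.023) and ribosomal proteins at -0.010 ± 0.046 (-0.10 to 0.084). Absorptive colonocyte markers were at 0.18 ± 0.14, goblet cell markers at -0.005 ± 0.070 and tight junction genes at 0.009 ± 0.048.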
